A study of Mus musculus with 27 samples.

How the data were processed

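LAM-HTGTS junctions were analysed from 27 samples, 3 libraries of each of 9 CH12F3 clones. Per the submitters' processing notes, the authors used Bowtie2 and the mm9 build; other steps are not given in the sources used here. The deposited tables list 1 junction per line, with the positions of the bait and prey alignments on the read and on the genome, and 1 table pools the 3 libraries of a clone. A library column told the libraries apart but not which replicate number each was, so libraries were numbered by name only. No value columns were left unused for lack of a sample.

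Overlap was the number of read bases shared by the bait and prey alignments. Values above 0 were counted as microhomology, 0 as direct and values below 0 as insertions. The bait window extended 10 kb to each side of the bait alignments (chromosome 12, 114664780 to 114664913), and the Sα window was 20 kb centred on the densest 1 kb bin at least 50 kb from the bait. The core was the shortest interval that held 90% of Sα junctions with clones weighted equally. The 11 measures were the share of junctions outside the bait window in the Sα window, the direct, microhomology and insertion shares, mean microhomology length, the share outside the core, bait length, the deletional share, and the shares on other chromosomes, in the bait window and between the windows. A further 8 measures were added after seeing the data. A contrast between clones grouped by their measured values was also computed and is not reported, because the grouping came from the outcome.

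The unit of the planned tests was the clone, as the mean of its libraries. These tests assume independent clones, which may not hold, because the labels say that the double mutants were derived from a PAXX-/- clone. Genotypes were compared by an exact permutation test of the sum of squares between them over 945 splits. The double mutant and Ligase4-/- were each compared with the 5 WT, PAXX-/- and XLF-/- clones by exact two-sided permutation of the mean difference over 21 splits. Benjamini-Hochberg adjustment covered these 33 tests. The tests, alternatives and the rule for naming regions (switch-region windows, and the 5 densest 10 kb windows outside the bait chromosome held by at least 5 files) were fixed before the data were examined. Comparisons by library were chosen after seeing the data, in place of values side by side, and used exact two-sided permutation with intervals from inverting that test, adjusted over 99 tests. They treat the libraries as replicates, and nothing in the labels says that these came from separate cultures, so their p-values may measure technical spread. Fisher's exact tests between pooled files, which compare files only, passed in 121 of 144 cases after adjustment. The interaction of XLF and PAXX loss was tested by 100000 residual permutations over 21 libraries, and was added after seeing the data.

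Libraries held 3610 to 14524 junctions. Intervals of single shares are exact Clopper-Pearson 95% intervals and, like the upper limits for counts of 0, which use 3 counts, cover counting error only. Lines repeating the junction, strand and bait end of another in the same library were 0.565% to 1.30% of a file. Libraries of 1 clone shared 3.77% to 13.4% of exact junctions and those of different clones 1.74% to 14.2%, and no pair stood apart as the same library. Read names showed 8 sequencing runs. PAXX-/- and XLF-/- shared 2 of them, and WT, XLF-/-PAXX-/- and Ligase4-/- shared none with another genotype.

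The tests were tried on 500 simulated data sets. Simulated libraries were drawn independently around 1 mean, with no clone or run effect. Calibration for libraries nested in clones and runs was therefore not tested. Without a difference, 4.0% fell under 0.05 for 6 against 3 libraries and 4.0% for the genotype test over 9 clones. With a simulated difference of -11 points between 6 and 3 libraries, 100% were called and 96.0% of intervals held it. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used. The planned comparison of lists of AID off-target and long fragile genes was not run, because gene positions in mm9 were not used here, and the genes of named windows are not given for the same reason. Individual Sγ and Sε regions were not separated for that reason either. Stimulation doses were not used here.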

Results

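Junctions between an immunoglobulin heavy chain bait and the rest of the genome were sequenced in CH12F3 cells, a mouse B-cell line that switches from IgM to IgA when stimulated. The method, linear amplification-mediated high-throughput genome-wide translocation sequencing (LAM-HTGTS), reads from a fixed bait at the 5′ side of the Sμ switch region into whatever DNA (the prey) was joined to it. The 27 samples were 3 libraries from each of 9 clones after 72 h of stimulation. WT was 1 parental line, and PAXX-/-, XLF-/-, XLF-/-PAXX-/- and Ligase4-/- were 2 clones each. PAXX, XLF and DNA ligase 4 are factors of classical non-homologous end joining, and the series asks whether PAXX and XLF are redundant. The files held 193201 junctions, from 11504 in WT to 38298 in Ligase4-/- clone 1, and single libraries held 3610 to 14524. Because WT was a single clone, comparisons with it by library measure the spread between libraries and not between clones. Comparisons by library between 2 mutant genotypes also shuffled libraries without regard to clone. Their p-values are therefore not evidence at the level of clones.

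Junctions in the Sα window, the acceptor region of the switch to IgA (chromosome 12, 114489501 to 114509500, mm9), differed in structure between genotypes. Direct joins, with neither shared nor inserted bases, made up 18.4% ± 0.206 (SD, n = 3 libraries) of Sα junctions in WT, 17.1% ± 0.481 and 16.6% ± 0.762 in the PAXX-/- clones, and 6.44% ± 0.263 and 6.06% ± 0.272 in the XLF-/- clones. The XLF-/-PAXX-/- clones gave 5.94% ± 0.245 and 5.75% ± 0.293, and the Ligase4-/- clones 6.0% ± 0.300 and 6.54% ± 1.47. The share with microhomology was 54.3% ± 0.960 in WT, 55.1% ± 1.63 and 51.7% ± 1.49 in PAXX-/-, and 70.8% to 76.8% by clone in the other genotypes. Differences between the 5 genotypes passed the planned exact permutation test over the 9 clones for the direct share (p = 0.00529, adjusted p = 0.0489) and the microhomology share (p = 0.00635, adjusted p = 0.0489). The insertion share also passed (exact permutation p = 0.00635, adjusted p = 0.0489), and mean microhomology length did so before adjustment only (exact permutation p = 0.0233, adjusted p = 0.0960). Substituted bait bases read as insertions, described below, may account for part of the insertion differences. At junctions on other chromosomes the same test called none of these 4 measures, and the genotypes accounted for 64.7% of the sum of squares of the direct share (exact permutation p = 0.286) against 99.9% at Sα. In the bait window, measured after seeing the data, the direct share was 20.1% in WT, 18.2% and 17.2% in PAXX-/-, and 6.55% to 7.80% by clone in the other genotypes. Genotypes accounted there for 99.7% of its sum of squares (exact permutation p = 0.00529, adjusted p = 0.0635) and 99.4% of that of the microhomology share (exact permutation p = 0.00212, adjusted p = 0.0508), and neither passed after adjustment.

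**Figure D1:**
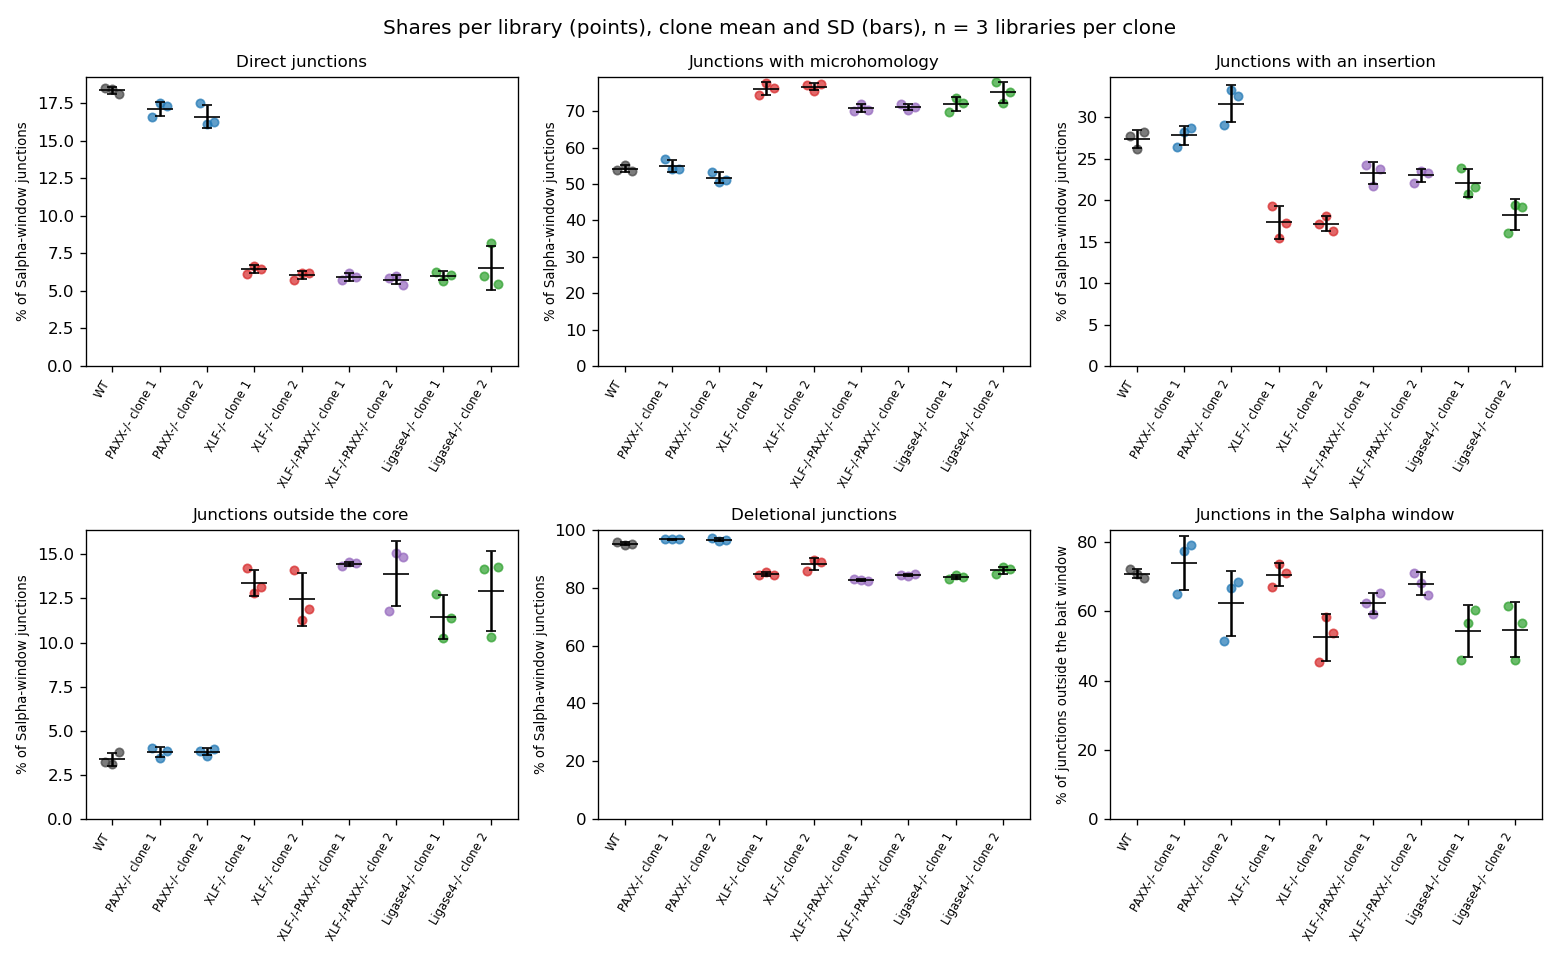
Each panel plots a share in percent on the vertical axis for the 9 clones, with 1 point per library and bars for the clone mean and SD (n = 3). WT and PAXX-/- clones lie at 16.6% to 18.4% direct joins and the other clones at 5.75% to 6.54%.

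With PAXX alone lost, the microhomology share at Sα differed from WT by -0.869 percentage points (95% interval -4.74 to 3.27, exact permutation p = 0.607, 6 against 3 libraries), and mean microhomology length by 0.00660 bases (-0.0473 to 0.0605, exact permutation p = 0.857). The direct share was 1.48 points lower, a difference of -1.48 (-2.36 to -0.635, exact permutation p = 0.0238, adjusted p = 0.0437). Deletional junctions, in the orientation that removes the DNA between Sμ and Sα, were 1.51 points more frequent (0.820 to 2.20, exact permutation p = 0.0119, adjusted p = 0.0251). Junctions between the Sα and bait windows were less frequent, 0.496% against 1.41% of those outside the bait window, a difference of -0.911 points (-1.24 to -0.637, exact permutation p = 0.0119, adjusted p = 0.0251). Some clones carried base substitutions within the bait. Among bait ends clear of these positions, a restriction chosen after seeing the data, the direct share no longer passed (-2.02, exact permutation p = 0.0595). The insertion share, which differed by 2.35 points over all bait ends (-1.74 to 7.10, exact permutation p = 0.155), passed there (4.80, 1.87 to 8.14, exact permutation p = 0.0119), as did the microhomology share (-2.78, -4.59 to -1.06, exact permutation p = 0.0238). Without insertions in the denominator the microhomology share differed in the other direction, by 1.26 points (exact permutation p = 0.0238). The restriction of bait ends drops longer baits in every clone, and WT carried no substitution as a main base. Under it the insertion share went from 27.4% to 21.8% in WT and from 29.7% to 26.6% in PAXX-/-. The microhomology share went from 54.3% to 60.6% and from 53.4% to 57.8%. The restricted values therefore compare another set of junctions and do not isolate the substitutions. PAXX-/- and WT libraries came from different sequencing runs, so run and genotype cannot be told apart here.

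Joint structure in XLF-/- differed from WT by much more than that in PAXX-/-. XLF-/- and WT libraries came from different sequencing runs, and WT was a single clone. Run and genotype therefore cannot be told apart in the values against WT. Against WT, the direct share differed by -12.1 points (95% interval -12.7 to -11.5), the microhomology share by 22.2 (20.3 to 24.1), the insertion share by -10.1 (-12.3 to -8.10) and microhomology length by 0.540 bases (0.471 to 0.615). Each gave an exact permutation p of 0.0119, the smallest that 6 against 3 libraries allow, with an adjusted p of 0.0251. Some Sα insertions equalled the continued bait with only 1 base changed, G to A at bait position 56 (G56A) or 68 (G68A). These were 2.84% and 2.12% of insertions in WT and 2.42% and 1.54% in PAXX-/- clone 1. In XLF-/- they were 0.170% and 0.283% in clone 1 and 0.0994% and 0% in clone 2. A substituted bait base read as an insertion may account for part of the insertion difference, and how much was not tested. Against PAXX-/-, which shared both of its sequencing runs with XLF-/-, the direct share differed by -11.1 points within the first shared run and -10.4 within the second. At junctions on other chromosomes none of the shares was called against WT, and microhomology length differed by -0.466 bases (exact permutation p = 0.0357), the opposite direction to Sα. Unaligned gaps over 20 bases were in 24.0% of those junctions in WT and in 16.7% and 21.9% in the XLF-/- clones. Stratified by run, the Sα difference of the direct share from PAXX-/- was -10.6 (exact permutation p = 0.00476), and that of the microhomology share 23.1 (exact permutation p = 0.00476).

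Over all bait ends, cells lacking both XLF and PAXX had more insertions and a lower microhomology share at Sα than cells lacking XLF alone. A substituted bait base read as an insertion may account for part of this. In the double-mutant clones, 10.0% and 10.9% of Sα insertions equalled the continued bait with only that base changed. Insertions of 1 base were in the total but could not count as a match. They were 5.94% and 5.67% of Sα junctions in these clones, against 4.49% and 3.96% in the XLF-/- clones. Microhomology length differed between the 2 genotypes by -0.0304 bases (95% interval -0.0838 to 0.0285, exact permutation p = 0.225) and the direct share by -0.401 points (-0.775 to -0.0244, exact permutation p = 0.0368, adjusted p = 0.0639). Insertions were 5.88 points more frequent in the double mutant (4.28 to 7.41, exact permutation p = 0.00216, adjusted p = 0.0126). The microhomology share differed by -5.48 points (-6.90 to -4.05, exact permutation p = 0.00216, adjusted p = 0.0126) and the deletional share by -2.90 (-5.20 to -0.731, exact permutation p = 0.0130, adjusted p = 0.0268). The deletional difference was -1.19 without XLF-/- clone 2 and -2.07 without XLF-/-PAXX-/- clone 1, neither of which passed, and -4.60 without XLF-/- clone 1. Without insertions in the denominator the microhomology share differed by -0.0555 points (exact permutation p = 0.766). Among bait ends that stopped before the substituted bait positions the insertion difference was 1.82 points (0.613 to 3.03, exact permutation p = 0.0108), and that of the microhomology share no longer passed (-1.40, -3.05 to 0.220, exact permutation p = 0.0649). The double mutant had a sequencing run of its own, so run and genotype cannot be told apart. The planned contrast of the 2 double-mutant clones with the 5 WT, PAXX-/- and XLF-/- clones passed for none of the 11 measures. Its lowest exact permutation p was 0.0952, for the deletional share, where 21 splits allow 0.0476. In the matching Ligase4-/- contrast, even that smallest exact permutation p had an adjusted p of 0.157. The comparison clones also included XLF-/-, so the contrast cannot decide whether PAXX and XLF are redundant.

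The direct share differed between the double mutant and Ligase4-/- by -0.424 points (95% interval -1.37 to 0.289, exact permutation p = 0.413), and microhomology length by -0.00319 bases (-0.0546 to 0.0492, exact permutation p = 0.894). The microhomology share was 71.0% against 73.6% (-2.53, -5.25 to 0.0267, exact permutation p = 0.0519) and the share outside the Sα core 14.2% against 12.2% (1.99, -0.0218 to 4.10, exact permutation p = 0.0541). Neither was called, but the first gained a call in 5 of 12 alternatives, with up to -3.37 points without reads with gaps over 20 bases, and changed sign in 3, and the second gained a call in 7 of 11. Without Ligase4-/- clone 1 the microhomology share was called at -4.17, and without its library 1 at -3.28. The share outside the core was called without XLF-/-PAXX-/- clone 2 (2.27) or its library 1 (2.46), and without Ligase4-/- clone 2 (2.72) or its library 1 (2.38) or 3 (2.41). The Sα share of junctions outside the bait window was 10.6 points higher in the double mutant (3.0 to 18.4, exact permutation p = 0.00866, adjusted p = 0.0251), and without XLF-/-PAXX-/- clone 2 it was 7.80 points and did not pass. The share between the Sα and bait windows differed by -1.98 points (-2.81 to -1.12, exact permutation p = 0.00433, adjusted p = 0.0226). The bait-window share was 4.19 points higher in the double mutant (1.64 to 6.59, exact permutation p = 0.00649, adjusted p = 0.0251), and 3.45 without XLF-/-PAXX-/- clone 2, which did not pass. Bait alignments were 1.97 bases longer (0.671 to 3.31, exact permutation p = 0.0108, adjusted p = 0.0251), and 1.56 without Ligase4-/- clone 2, which did not pass. Insertions were 2.96 points more frequent (0.383 to 5.46, exact permutation p = 0.0238, adjusted p = 0.0437). That call was lost without XLF-/-PAXX-/- clone 1 (2.82) or clone 2 (3.09), without Ligase4-/- clone 2 (1.04), with identical junctions collapsed (2.55) and after thinning (2.37), and the difference was -1.27 among bait ends clear of substitutions. Junctions on other chromosomes differed by -7.19 points (-13.8 to -0.716, exact permutation p = 0.0281), which did not pass after adjustment (adjusted p = 0.0506). The unadjusted call was also lost without XLF-/-PAXX-/- clone 1 (-9.63) or clone 2 (-4.76), without Ligase4-/- clone 2 (-6.56), and without library 3 of XLF-/-PAXX-/- clone 1 (-7.19) or library 1, 2 or 3 of clone 2 (-6.34, -6.60 and -7.18). In the planned contrast with the 5 WT, PAXX-/- and XLF-/- clones, Ligase4-/- had shorter bait alignments by a difference of -2.82 bases and 3.37 points more junctions between the Sα and bait windows. Both reached the smallest exact permutation p of 0.0476, and neither passed after adjustment (adjusted p = 0.157). Runs of the double mutant and Ligase4-/- held no other genotype.

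**Figure D2:**
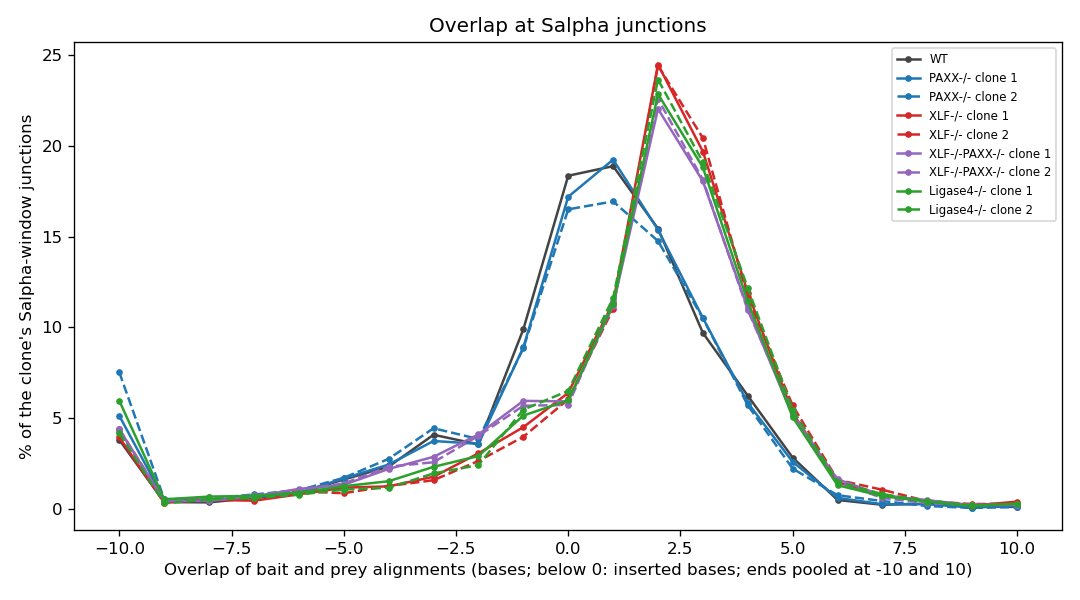
The horizontal axis is the overlap of bait and prey alignments in bases (negative values are inserted bases) and the vertical axis the percent of each clone's Sα junctions, with 1 line per clone. Lines of WT and PAXX-/- clones peak at lower overlaps, and exactly 2 shared bases occurred in 15.5% of WT junctions against 24.5% in XLF-/- clone 1.

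Junctions also spread further from the Sα core, the 6161 bp interval from 114496668 to 114502828 that held 90% of junctions with all clones weighted equally. Outside it lay 3.37% ± 0.359 (SD, n = 3 libraries) of Sα junctions in WT and 3.79% ± 0.295 and 3.81% ± 0.201 in the PAXX-/- clones. The XLF-/- clones had 13.4% ± 0.730 and 12.5% ± 1.49, the XLF-/-PAXX-/- clones 14.5% ± 0.110 and 13.9% ± 1.83, and the Ligase4-/- clones 11.5% ± 1.25 and 12.9% ± 2.27. The genotypes differed in the planned test (exact permutation p = 0.00741, adjusted p = 0.0489), and without XLF-/-PAXX-/- clone 1 the value was 99.1% of the sum of squares and no longer passed, with fewer splits. Deletional junctions were 95.3% ± 0.549 of the total in WT, 96.9% and 96.8% in the PAXX-/- clones and 82.8% to 88.2% by clone in the rest (exact permutation p = 0.0169 over the 9 clones, adjusted p = 0.0798). The median deletional position was 114500087 in WT and 114499304 in XLF-/- clone 1, further from the bait.

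**Figure D3:**
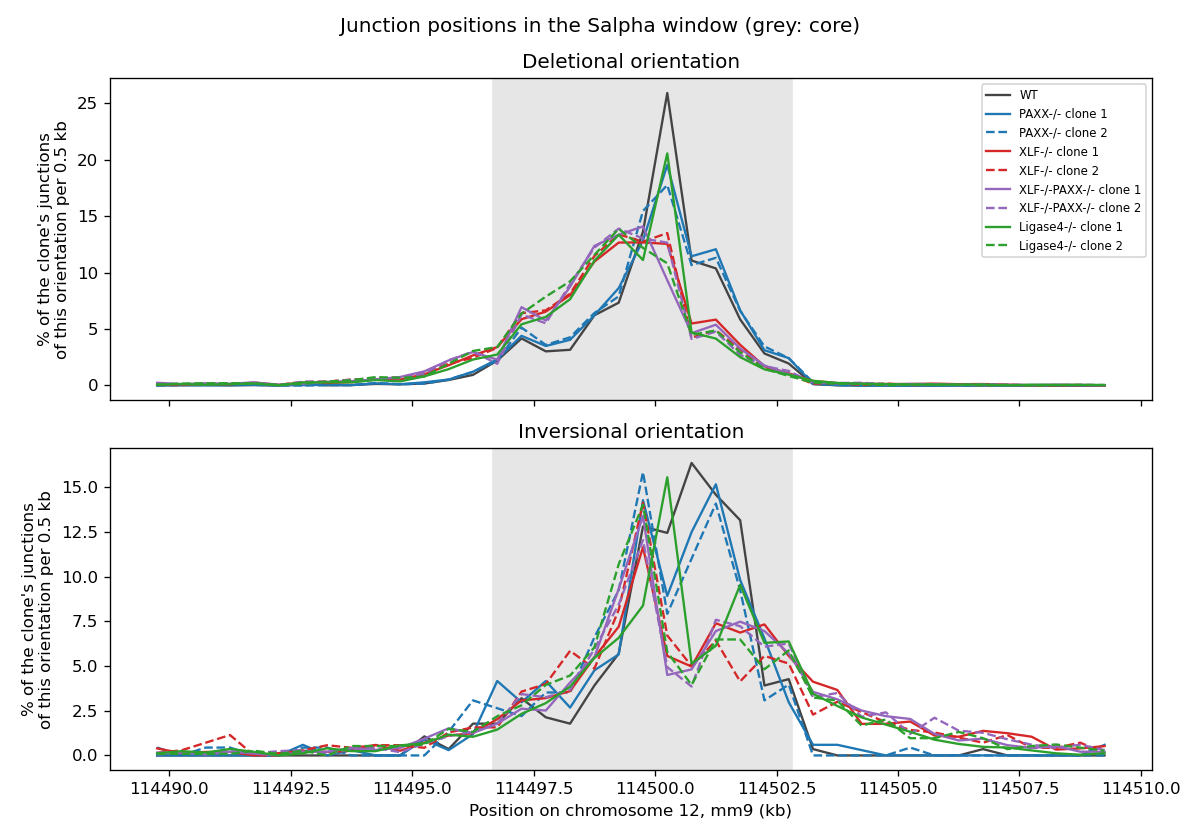
The horizontal axis is the position on chromosome 12 (mm9, kb) and the vertical axis the percent of a clone's junctions of 1 orientation per 0.5 kb, with 1 line per clone and the core shaded. In the inversional panel, the share above the core was 1.42% in WT, 2.35% and 2.17% in the PAXX-/- clones and 16.8% to 22.4% in XLF-/-, XLF-/-PAXX-/- and Ligase4-/- clones.

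Among inversional Sα junctions, a measure added after seeing the data, the part beyond the bait-proximal edge of the core was 1.42% ± 1.56 in WT (4 of 281 junctions) and 2.35% and 2.17% in the PAXX-/- clones. It was 22.4% and 17.8% in the XLF-/- clones, 20.8% and 21.8% in XLF-/-PAXX-/-, and 16.8% and 17.8% in Ligase4-/- (exact permutation p = 0.0169 over the 9 clones, adjusted p = 0.0863, which does not pass). In the bait window itself, deletional junctions over 3 kb from the bait were 0.660% ± 0.100 of those below it in WT and 1.53% and 2.03% in the PAXX-/- clones. They were 19.7% to 25.4% by clone in the other genotypes (exact permutation p = 0.0180 over the 9 clones, adjusted p = 0.0863, which does not pass).

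The share of junctions that reached Sα was 70.9% ± 1.37 (SD, n = 3 libraries) in WT, 73.9% ± 7.73 and 62.3% ± 9.41 in PAXX-/-, 70.6% ± 3.41 and 52.5% ± 6.72 in XLF-/-, 62.4% ± 3.09 and 68.0% ± 3.30 in XLF-/-PAXX-/-, and 54.4% ± 7.49 and 54.8% ± 8.05 in Ligase4-/-. The planned exact permutation test called no difference between genotypes (p = 0.490). By library, the Sα share differed from WT by -16.4 points in Ligase4-/- (95% interval -26.5 to -6.19, exact permutation p = 0.0119, adjusted p = 0.0251, 6 against 3 libraries). The differences were -2.80 in PAXX-/- (exact permutation p = 0.726), -9.35 in XLF-/- (exact permutation p = 0.250) and -5.71 in XLF-/-PAXX-/- (exact permutation p = 0.0833), and the last gained a call in 7 of 13 alternatives and without XLF-/-PAXX-/- clone 2 library 1 (-6.92), and was 0.409 among bait ends clear of substitutions. That of PAXX-/- was 3.01 without clone 2 and 0.524 without library 1 of clone 2. The XLF-/- difference was -0.299 without its clone 2 and -18.4 without its clone 1, and it gained a call in 2 of 13 alternatives. The Ligase4-/- call was lost among bait ends clear of substitutions (-8.37, exact permutation p = 0.107) and without WT library 1, 2 or 3 (-15.6, -16.5 and -16.98). It was also lost without Ligase4-/- clone 1 (-16.1) or clone 2 (-16.6), where 20 splits allow no exact p under 0.1. Each substitution was in at most 1.60% of WT or Ligase4-/- reads. The loss among bait ends clear of substitutions is therefore not explained by substituted reads. That restriction drops longer baits in every clone, and what caused the loss was not tested. No run held both Ligase4-/- and WT. In 4 of 4 PAXX-/- and XLF-/- clones the library of the first shared run had the lowest Sα share and the highest share on other chromosomes. Within clones that run differed from the second by -11.5 points for the Sα share and 8.61 for other chromosomes, a test chosen after seeing the data (exact permutation p = 0.0123 for both, the smallest that 81 splits allow, adjusted p = 0.0679, which does not pass). The Sα share of XLF-/- differed from PAXX-/- by -2.15 points within the first shared run, -8.74 within the second and -6.55 stratified by run (exact permutation p = 0.243). With the denominator limited to the span from the Sα window to the bait window, the planned genotype test gave 95.9% of the sum of squares between genotypes (exact permutation p = 0.00847), so the call depends on the denominator. Junctions on other chromosomes were 18.3% ± 1.24 in WT and 13.5% to 27.1% by clone elsewhere (exact permutation p = 0.793). Junctions between the Sα and bait windows were 1.41% ± 0.0979 in WT, 0.385% and 0.607% in PAXX-/-, 2.14% and 2.30% in XLF-/-, 2.22% and 3.28% in XLF-/-PAXX-/-, and 5.13% and 4.34% in Ligase4-/- (exact permutation p = 0.00635 over the 9 clones, adjusted p = 0.0489). This span was not uniform. At 114600000 to 114604999, Ligase4-/- clones held 1.43% and 1.19% of all junctions, WT 0.539% and XLF-/- clones 0.0327% and 0.290%. At 114650000 to 114654999, next to the bait window, WT held 0. The XLF-/- clones held 0.411% and 0.303% there and the Ligase4-/- clones 0.225% and 0.355%.

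Outside chromosome 12, the densest 10 kb window was 32420000 to 32429999 on chromosome 14. It held 0.287% of WT junctions (95% exact Clopper-Pearson interval 0.198 to 0.403) and 0.533% to 0.869% in the PAXX-/-, XLF-/-, XLF-/-PAXX-/- clones and Ligase4-/- clone 2. Ligase4-/- clone 1 had 0 of 38298 junctions there, which allows a share of up to 0.00783%. The window at 125950000 on chromosome 8 held 164 junctions of that clone, 0.428% (0.365 to 0.499), against 0.0174% to 0.120% in the others. The window at 20660000 on chromosome 1 held 208 junctions over all files, 190 of them at 1 position, with a median prey alignment of 26 bases. Windows at 129110000 on chromosome 8 and 115440000 on chromosome 14 held 162 and 117 junctions. Ligase4-/- clone 1 held 92 and 44 of them. These were 0.240% and 0.115% of its junctions, against 0.00674% to 0.0894% and 0 to 0.0809% in the other clones.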

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

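The interaction tests, the comparisons by library, the bait restrictions and the tests of sequencing run and long gaps were chosen only after the results were seen. The search for C57T in inserted bases was set before its result was seen.

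The lower direct share of XLF-/-, XLF-/-PAXX-/- and Ligase4-/- clones was weighed against 3 technical explanations. For XLF-/- against PAXX-/-, sequencing run as the cause is argued against by the run-stratified difference of -10.6 points. For the same pair, substituted bait positions are argued against by the difference of -9.63 points among bait ends clear of them, and long unaligned gaps by -11.11 points without such reads. For XLF-/-, the double mutant and Ligase4-/- against WT, run and genotype cannot be told apart. WT shared 0 runs with them, and its single run held no other genotype. Within genotypes, the direct share was 5.67% to 6.54% over the 4 runs of Ligase4-/- and 5.95% and 6.39% in the 2 runs of XLF-/-. It was 17.04% and 16.8% in those of PAXX-/-. Genotype stays among the open explanations.

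The effect of PAXX loss differed with and without XLF in 4 of 11 measures over 21 libraries (residual permutation, Benjamini-Hochberg). The interaction was 1.08 points for the direct share, -4.61 for the microhomology share, -4.41 for the deletional share and 1.44 for the share between the windows. WT and the double mutant each had a run of their own, so run and interaction cannot be told apart. The test shuffled libraries without regard to clone, and WT was a single clone, so differences between clones can count as interaction. Among bait ends clear of substitutions the microhomology interaction changed sign, to 1.38 points. The insertion interaction, 3.53 points and not called after adjustment, changed sign there and passed the threshold in the new direction. On the log odds scale the direct interaction was 0.0324 and was not called, and it also lost its call after thinning. Counting microhomology from 4 bases, the microhomology interaction lost its call. At junctions on other chromosomes both the direct and the microhomology interaction changed sign.

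The insertion share was 5.88 points higher in the double mutant than in XLF-/-. A substituted bait base read as an insertion may account for part of it: in the lower of the 2 double-mutant clones, 10.0% of Sα insertions equalled the continued bait with only C57T changed, against at most 0.339% in clones without that substitution and 2.91% in PAXX-/- clone 2, which carried it in 41.4% of reads. Only insertions of 2 or more bases could count as a match, out of all insertions. As the whole cause it is argued against, by library only, by a difference of 1.82 points (95% interval 0.613 to 3.03) among bait ends that stopped before it. Those are another set of junctions, so 1.82 is not the remainder of 5.88. The WT insertion share, without that substitution, was 27.4% over all bait ends and 21.8% among them. What causes the 1.82 points stays open, because the double mutant had a sequencing run of its own.

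Among 44 groups of 6 libraries, 3 held a library far from the others, where chance flags about 1 in 20 groups, or 2.2. Mean microhomology length was 2.28 bases in PAXX-/- clone 1 library 3, against 2.34 to 2.37 in the other PAXX-/- libraries. The share outside the core was 11.8% in XLF-/-PAXX-/- clone 2 library 1, against 14.3% to 15.1%. The direct share was 8.20% in Ligase4-/- clone 2 library 2, against 5.44% to 6.25%.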

How the results depend on the processing

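The 11 measures were recomputed in 11 comparisons (the genotype test, both planned contrasts, 7 comparisons by library and the interaction), each under the 4 to 15 alternatives run for it. The other 2 comparisons by library were not recomputed. Apart from leaving out a clone or library, 931 values kept their direction and side of the exact or permutation threshold, 41 lost a call, 49 gained one and 57 changed sign, 6 of them past the threshold in the new direction. The comparisons by library, the interaction, the run-stratified fit, the limit on gaps and both restrictions of bait ends were added after seeing the data. The restriction to bait ends clear of substitutions drops longer baits in every clone, also in clones without a substitution. The genotype test gives the percent of the sum of squares between genotypes, and other values are differences in percentage points or bases, or in log odds on that scale. No paired analysis was possible by replicate number because the library names carry none, and XLF-/- against PAXX-/- was blocked by sequencing run instead. Mapping quality is not in the tables used here, so that alternative was not run, and the gene lists were not run. Within-run values need 2 genotypes in a run, which XLF-/- and PAXX-/- alone had. Except where libraries replaced clones as the unit, which adds units, or fewer clones leave fewer splits, the cause of a change was not tested.

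With all junctions as the denominator, the Sα share (-10.1 in XLF-/- against WT, -8.11 in XLF-/-PAXX-/- against WT) gained a call. With the span from Sα to the bait window as the denominator, the Sα share (95.9 in the genotype test, -5.88 in the Ligase4 contrast, -1.62 in XLF-/- against WT, -2.81 in XLF-/- against PAXX-/-, -2.08 in XLF-/-PAXX-/- against WT) gained a call. The Sα share (1.20 in PAXX-/- against WT, -1.66 in the interaction) changed sign and passed the threshold in the new direction there. The Sα share (-0.458 in XLF-/-PAXX-/- against XLF-/-) changed sign there. With a 5 kb bait window, the Sα share (-7.74 in XLF-/-PAXX-/- against WT) gained a call. The bait-window share (2.79 in XLF-/- against WT) lost the call there. The bait-window share (-0.175 in Ligase4-/- against WT) changed sign there. With a 20 kb bait window, the between share (0.195 in XLF-/- against WT, 0.610 in XLF-/-PAXX-/- against WT) lost the call. The bait-window share (3.74 in XLF-/- against PAXX-/-) gained a call there. With a 10 kb Sα window, the Sα share (-8.44 in XLF-/-PAXX-/- against WT) gained a call. With a 40 kb Sα window, the outside-core share (2.35 in XLF-/-PAXX-/- against Ligase4-/-, 1.53 in XLF-/-PAXX-/- against XLF-/-) gained a call. With identical junctions collapsed, the insertion share (2.55 in XLF-/-PAXX-/- against Ligase4-/-) lost the call. The outside-core share (0.443 in PAXX-/- against WT, 2.06 in XLF-/-PAXX-/- against Ligase4-/-) gained a call there. With prey of at least 50 bases, the Sα share (-8.23 in XLF-/-PAXX-/- against WT) and the microhomology share (-2.87 in XLF-/-PAXX-/- against Ligase4-/-) gained a call. The outside-core share (2.03 in XLF-/-PAXX-/- against Ligase4-/-) gained a call there. The direct share (-0.192 in XLF-/-PAXX-/- against XLF-/-) lost the call there. The microhomology length (-0.00145 in PAXX-/- against WT) and the other-chromosome share (0.449 in XLF-/- against PAXX-/-, 0.576 in XLF-/-PAXX-/- against WT) changed sign there. Counting microhomology from 2 bases, the microhomology share (-2.45 in XLF-/-PAXX-/- against Ligase4-/-) gained a call. The microhomology length (-0.0139 in PAXX-/- against WT, 0.00804 in XLF-/-PAXX-/- against Ligase4-/-, 0.0130 in the interaction) changed sign there. Counting it from 4 bases, the microhomology share (-0.830 in the interaction) and the microhomology length (0.0640 in Ligase4-/- against WT) lost the call. The microhomology length (0.0223 in XLF-/-PAXX-/- against Ligase4-/-) changed sign there. Without insertions in the denominator, the direct share (0.0555 in XLF-/-PAXX-/- against XLF-/-) and the microhomology share (0.257 in XLF-/-PAXX-/- against Ligase4-/-) changed sign. The microhomology share (1.26 in PAXX-/- against WT) changed sign and passed the threshold in the new direction there. The microhomology share (-0.0555 in XLF-/-PAXX-/- against XLF-/-) lost the call there. Among deletional junctions, the direct share (-0.478 in XLF-/-PAXX-/- against XLF-/-) lost the call. The microhomology share (-2.81 in XLF-/-PAXX-/- against Ligase4-/-) gained a call there. The microhomology length (0.00542 in XLF-/-PAXX-/- against Ligase4-/-) changed sign there. At junctions on other chromosomes, the direct share (64.7 in the genotype test, -1.59 in XLF-/- against WT, -2.48 in XLF-/- against PAXX-/-, -0.507 in XLF-/-PAXX-/- against XLF-/-, -2.10 in XLF-/-PAXX-/- against WT, -3.23 in Ligase4-/- against WT) and the microhomology share (30.7 in the genotype test, 4.29 in XLF-/- against WT, 3.64 in XLF-/- against PAXX-/-, 7.54 in XLF-/-PAXX-/- against WT, 1.51 in Ligase4-/- against WT) lost the call. The insertion share (24.99 in the genotype test, -2.69 in XLF-/- against WT, -1.17 in XLF-/- against PAXX-/-, -5.44 in XLF-/-PAXX-/- against WT) and the microhomology length (55.9 in the genotype test) lost the call there. The direct share (0.882 in PAXX-/- against WT, 1.13 in XLF-/-PAXX-/- against Ligase4-/-, -1.39 in the interaction) and the microhomology share (-0.457 in the Ligase4 contrast, 0.643 in PAXX-/- against WT, 6.03 in XLF-/-PAXX-/- against Ligase4-/-, 3.26 in XLF-/-PAXX-/- against XLF-/-, 2.61 in the interaction) changed sign there. The insertion share (3.41 in the Ligase4 contrast, -1.53 in PAXX-/- against WT, -7.16 in XLF-/-PAXX-/- against Ligase4-/-, -2.75 in XLF-/-PAXX-/- against XLF-/-, 1.72 in Ligase4-/- against WT, -1.22 in the interaction) and the microhomology length (-0.214 in the double-mutant contrast, -0.301 in PAXX-/- against WT, -0.165 in XLF-/- against PAXX-/-, -0.261 in Ligase4-/- against WT, 0.246 in the interaction) changed sign there. The microhomology length (-0.466 in XLF-/- against WT, -0.520 in XLF-/-PAXX-/- against WT) changed sign and passed the threshold in the new direction there. For a core of 80%, the outside-core share (2.02 in PAXX-/- against WT, 2.18 in XLF-/-PAXX-/- against Ligase4-/-) gained a call. The outside-core share (-1.09 in the interaction) changed sign there. For a core of 95%, the outside-core share (1.30 in XLF-/-PAXX-/- against Ligase4-/-) gained a call. Over all junctions outside the bait window, the bait length (-1.80 in the Ligase4 contrast) lost the call. The bait length (0.462 in the interaction) changed sign there. After thinning to the smallest file, the direct share (-0.480 in XLF-/-PAXX-/- against XLF-/-, 1.09 in the interaction) and the insertion share (2.37 in XLF-/-PAXX-/- against Ligase4-/-) lost the call. The microhomology length (0.00369 in XLF-/-PAXX-/- against Ligase4-/-) changed sign there. The outside-core share (2.51 in XLF-/-PAXX-/- against Ligase4-/-) gained a call there. Without reads with gaps over 20 bases, the Sα share (-7.82 in XLF-/-PAXX-/- against WT) and the microhomology share (-3.37 in XLF-/-PAXX-/- against Ligase4-/-) gained a call. The outside-core share (0.445 in PAXX-/- against WT) and the bait-window share (3.48 in XLF-/- against PAXX-/-) gained a call there. The microhomology share (0.0971 in PAXX-/- against WT) and the other-chromosome share (0.444 in XLF-/-PAXX-/- against WT) changed sign there. Among bait ends clear of substitutions, the Sα share (2.88 in the double-mutant contrast, 0.409 in XLF-/-PAXX-/- against WT) and the microhomology share (2.07 in XLF-/-PAXX-/- against Ligase4-/-, 1.38 in the interaction) changed sign. The insertion share (-1.27 in XLF-/-PAXX-/- against Ligase4-/-) and the microhomology length (0.0118 in XLF-/-PAXX-/- against Ligase4-/-, 0.00967 in XLF-/-PAXX-/- against XLF-/-) changed sign there. The Sα share (-8.37 in Ligase4-/- against WT) and the direct share (-2.02 in PAXX-/- against WT, -0.417 in XLF-/-PAXX-/- against XLF-/-) lost the call there. The microhomology share (-1.40 in XLF-/-PAXX-/- against XLF-/-) and the insertion share (-1.25 in Ligase4-/- against WT) lost the call there. The microhomology share (-2.78 in PAXX-/- against WT) and the insertion share (4.80 in PAXX-/- against WT) gained a call there. The outside-core share (1.81 in XLF-/-PAXX-/- against Ligase4-/-, 1.24 in XLF-/-PAXX-/- against XLF-/-) and the deletional share (-1.91 in XLF-/-PAXX-/- against Ligase4-/-) gained a call there. The insertion share (-2.98 in the interaction) changed sign and passed the threshold in the new direction there. For baits at least 10 bases past the shortest, the Sα share (-8.31 in XLF-/-PAXX-/- against WT) and the microhomology share (-3.02 in XLF-/-PAXX-/- against Ligase4-/-) gained a call. The bait-window share (3.47 in XLF-/- against PAXX-/-) gained a call there. The direct share (-0.406 in XLF-/-PAXX-/- against XLF-/-) and the bait length (54.1 in the genotype test, -1.06 in the Ligase4 contrast, -0.114 in XLF-/- against PAXX-/-) lost the call there. The microhomology length (-0.00277 in PAXX-/- against WT) and the bait length (0.365 in the double-mutant contrast, 1.48 in XLF-/- against WT, 1.60 in XLF-/-PAXX-/- against WT, 0.173 in Ligase4-/- against WT) changed sign there. The other-chromosome share (0.676 in XLF-/-PAXX-/- against WT) changed sign there. With the replicate as the unit, the Sα share (36.03 in the genotype test, -11.5 in the Ligase4 contrast) and the direct share (-7.07 in the double-mutant contrast, -6.65 in the Ligase4 contrast) gained a call. The microhomology share (10.7 in the Ligase4 contrast) and the microhomology length (0.291 in the double-mutant contrast, 0.294 in the Ligase4 contrast) gained a call there. The outside-core share (6.82 in the double-mutant contrast, 4.84 in the Ligase4 contrast) and the deletional share (-8.79 in the double-mutant contrast, -7.46 in the Ligase4 contrast) gained a call there. The bait-window share (53.8 in the genotype test, 3.40 in the double-mutant contrast) and the between share (1.38 in the double-mutant contrast) gained a call there. On the log odds scale, the direct share (0.0324 in the interaction) and the between share (1.50 in the Ligase4 contrast) lost the call. The outside-core share (-0.0167 in the interaction) changed sign there. Within the second shared sequencing run, the bait length (-2.02 in XLF-/- against PAXX-/-) lost the call. The other-chromosome share (1.21 in XLF-/- against PAXX-/-) changed sign there.

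Leaving out each clone or library in turn kept 2288 values, while 136 lost a call, 28 gained one and 45 changed sign. Without WT or a clone of the pair, the planned contrasts have fewer splits and a call can be lost by that alone. The Sα share ranged from -4.24 to 1.98 in the double-mutant contrast, -8.61 to 3.01 in PAXX-/- against WT and -15.6 to 2.50 in XLF-/- against PAXX-/-. Sα share ranges were also -2.61 to 15.5 in the interaction, -5.41 to 12.7 in XLF-/-PAXX-/- against XLF-/- and 7.80 to 13.5 in XLF-/-PAXX-/- against Ligase4-/-. Sα share ranges were also -18.4 to -0.299 in XLF-/- against WT, -8.55 to -2.88 in XLF-/-PAXX-/- against WT and -17.8 to -14.6 in Ligase4-/- against WT. The insertion share ranged from -2.91 to 0.707 in the double-mutant contrast, 1.61 to 5.45 in the interaction and -10.7 to -9.72 in XLF-/- against WT. Insertion share ranges were also 1.04 to 4.87 in XLF-/-PAXX-/- against Ligase4-/-, -4.85 to -3.84 in XLF-/-PAXX-/- against WT and -9.12 to -5.30 in Ligase4-/- against WT. The microhomology length ranged from 99.5 to 99.8 in the genotype test, -0.0140 to 0.0246 in PAXX-/- against WT and 0.520 to 0.553 in XLF-/- against WT. Microhomology length ranges were also -0.0167 to 0.0103 in XLF-/-PAXX-/- against Ligase4-/-, 0.489 to 0.523 in XLF-/-PAXX-/- against WT and 0.493 to 0.526 in Ligase4-/- against WT. The outside-core share ranged from 97.7 to 99.7 in the genotype test, 0.289 to 0.629 in PAXX-/- against WT and 0.375 to 1.32 in the interaction. Outside-core share ranges were also 9.08 to 10.01 in XLF-/- against WT, 0.800 to 1.74 in XLF-/-PAXX-/- against XLF-/- and 1.26 to 2.72 in XLF-/-PAXX-/- against Ligase4-/-. Outside-core share ranges were also 10.5 to 11.3 in XLF-/-PAXX-/- against WT and 8.10 to 9.55 in Ligase4-/- against WT. The bait length ranged from 81.9 to 96.7 in the genotype test, -3.23 to -2.31 in the Ligase4 contrast and -0.0155 to 1.82 in PAXX-/- against WT. Bait length ranges were also -3.26 to -1.42 in XLF-/- against PAXX-/-, -1.44 to 0.397 in the interaction and -0.0936 to 0.816 in XLF-/-PAXX-/- against XLF-/-. Bait length ranges were also 1.56 to 2.38 in XLF-/-PAXX-/- against Ligase4-/- and -3.44 to -2.62 in Ligase4-/- against WT. The deletional share ranged from 94.7 to 98.5 in the genotype test, 1.24 to 1.79 in PAXX-/- against WT and -10.5 to -7.12 in XLF-/- against WT. Deletional share ranges were also -4.60 to -1.19 in XLF-/-PAXX-/- against XLF-/-, -2.50 to -0.176 in XLF-/-PAXX-/- against Ligase4-/- and -12.5 to -10.9 in XLF-/-PAXX-/- against WT. Deletional share ranges were also -11.5 to -9.22 in Ligase4-/- against WT. The bait-window share ranged from -1.93 to 0.393 in the Ligase4 contrast, 0.0877 to 2.81 in PAXX-/- against WT and 0.886 to 5.78 in XLF-/- against PAXX-/-. Bait-window share ranges were also -2.78 to 2.11 in the interaction, 2.34 to 7.23 in XLF-/- against WT and -1.33 to 3.56 in XLF-/-PAXX-/- against XLF-/-. Bait-window share ranges were also 3.05 to 5.33 in XLF-/-PAXX-/- against Ligase4-/- and 5.15 to 6.64 in XLF-/-PAXX-/- against WT. The between share ranged from 2.97 to 3.76 in the Ligase4 contrast, -1.02 to -0.799 in PAXX-/- against WT and 0.730 to 0.906 in XLF-/- against WT. Between share ranges were also 0.000490 to 1.05 in XLF-/-PAXX-/- against XLF-/-, 0.817 to 1.87 in XLF-/-PAXX-/- against WT and 2.93 to 3.72 in Ligase4-/- against WT. The direct share ranged from -1.75 to -1.22 in PAXX-/- against WT, -12.3 to -11.9 in XLF-/- against WT and -0.591 to -0.211 in XLF-/-PAXX-/- against XLF-/-. Direct share ranges were also -12.6 to -12.4 in XLF-/-PAXX-/- against WT and -12.5 to -11.8 in Ligase4-/- against WT. The microhomology share ranged from -2.53 to 0.792 in PAXX-/- against WT, 21.9 to 22.8 in XLF-/- against WT and -4.17 to -0.888 in XLF-/-PAXX-/- against Ligase4-/-. Microhomology share ranges were also 16.5 to 17.3 in XLF-/-PAXX-/- against WT and 17.7 to 20.9 in Ligase4-/- against WT. The other-chromosome share ranged from -1.74 to 6.93 in PAXX-/- against WT, -7.34 to 6.21 in XLF-/- against PAXX-/- and -12.5 to 1.01 in the interaction. Other-chromosome share ranges were also -4.74 to 8.81 in XLF-/- against WT, -9.94 to 3.60 in XLF-/-PAXX-/- against XLF-/- and -9.63 to -4.76 in XLF-/-PAXX-/- against Ligase4-/-. Other-chromosome share ranges were also -3.57 to 1.29 in XLF-/-PAXX-/- against WT.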

Other observations

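The test of unaligned gaps on chromosome 14, the depth test and the test of single libraries were chosen after their patterns were seen, and the test of reads with both substitutions was set before its result was seen.

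Reads showed which bases the bait carried in each clone. The bait read, chromosome 12, 114664900 down to 114664807 (mm9), was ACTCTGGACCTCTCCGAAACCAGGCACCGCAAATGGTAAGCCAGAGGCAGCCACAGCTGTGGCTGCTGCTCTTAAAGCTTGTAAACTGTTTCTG, with positions counted from 1 at its first base. PAXX-/- clone 2 carried G56A in 56.4% of reads and C57T in 41.4%, both within an AGCT motif. C57T was in 45.5% and 51.1% of reads of the XLF-/-PAXX-/- clones, and G68A in 47.8% of XLF-/- clone 1. In clones without them as a main base, G56A was in 1.06% of WT reads and 1.67% of PAXX-/- clone 1 reads, and in at most 0.560% elsewhere. G68A was in 1.60% of WT reads, 1.90% and 2.18% of reads of the PAXX-/- clones and at most 0.476% elsewhere, and C57T in 0.912% of PAXX-/- clone 1 reads, 0.523% of WT reads and at most 0.439% elsewhere.

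In PAXX-/- clone 2, 0.331% of the 5433 reads covering both positions held both substitutions and 2.43% held neither. This is consistent with 2 copies of the bait, each with 1 substitution. The labels say that the double mutants were derived from a PAXX-/- clone. C57T is shared with clone 2, but G56A was in only 0.352% and 0.290% of double-mutant reads, so descent from clone 2 as sequenced does not account for the other copy, and descent was not tested further.

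Ligase4-/- clone 1 held no junctions in the chromosome 14 window that every other clone filled. Depth is argued against by the 109.9 junctions expected at the lowest share of the other clones, and a single failed library by at least 30.4 expected in each of its 3 libraries. Of 116 unaligned gaps of 10 or more bases at this window, 77 (66.4%) held the switch-repeat units GAGCT or GGGCT, against 11.5% at other junctions on other chromosomes. With each prey position counted once per clone these were 23 of 56 (41.1%) and 11.4%. The share was higher at the window in 8 of the 8 clones with such gaps, which had 2 to 11 of these positions each, and no test over clones was run. A candidate explanation is a chromosome 14 segment carried inside a switch region in the other clones. The labels give 2 origins for the Ligase4-/- clones without saying which is which, and origin, genome and the authors' filtering cannot be told apart here.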
